A study of Homo sapiens with 4 samples.

How the data were processed

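Total RNA of Hs683 cells, a human glioma cell line, was measured on 4 Affymetrix expression arrays, 2 of cells given miR-20a and 2 of cells given a control microRNA of scrambled sequence (miR-NT). All 4 arrays came from cells in which QK, the gene now named QKI, had been knocked down. Per the labels' protocols, RNA was isolated with a column kit and 6 ug of it was turned into biotinylated cRNA. The deposited values are log2 expression values, 1 per probe set and array, judged from their range; a probe set is a group of short probes that report on the same transcript. The submitters' processing notes name the R package affy, with no version. The summarisation, the background correction, the normalization and the choice of the 20323 listed probe sets are not given in the sources used here. The table listed about 1 probe set per gene, so that probe sets of the same gene could be compared for few genes only.

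Samples were grouped by their titles and source names, and the replicate number was taken from the title. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these arrays, which may be technical. Probe sets were named through the platform annotation, with symbols updated through the gene identifiers in the RefSeq gene table, where 18034 identifiers matched. There were 18060 probe sets with 1 gene symbol, 886 with several and 1375 without a gene in the annotation, 1 of them a control. The 3 control probe sets, whose names begin with AFFX, were left out of the gene tests; those of ACTB and GAPDH were used to compare the arrays, and the other is not reported here. The remaining probe sets stood for 17716 genes, 338 of which had more than 1 probe set, and the probe set with the highest mean over all arrays was used for each gene. The 5315 dimmest genes (the lowest 30% by mean over all 4 arrays) were left out, which left 12401 genes. The files name no genome build, and no positions are printed.

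Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, miR-20a minus miR-NT, no covariate), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The fit had 2 residual degrees of freedom and 5.53 prior degrees of freedom, with a prior SD of 0.11 on the log2 scale. Standard errors given with a log2 fold change are those of this moderated fit. An exact permutation test of 2 arrays against 2 cannot give a p below 0.333, and none was run. For 18 gene lists, camera (limma) compared the members with all other tested genes at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. The lists were published miR-17/20a targets, TGF-beta receptors and SMAD pathway, TGF-beta-induced genes, extracellular matrix and adhesion, G1/S and DNA replication, G2/M and mitosis, p53 targets, interferon response, NF-kB and inflammatory cytokines, hypoxia, cholesterol synthesis, unfolded protein and amino acid stress, immediate early and heat shock, glial and neural lineage, immune cell markers, epithelial and endothelial markers, cytosolic ribosomal proteins and microRNA pathway proteins. Within each list, members were also counted at an adjusted p over the list alone.

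The tests, the lists, the alternatives and the rule for the genes named in the text were fixed before the data were examined. The rule took TGFBR2, QKI and MIR17HG wherever measured, then the 12 highest and 12 lowest fold changes past the threshold or, where fewer than 6 passed in a direction, the 6 with the smallest p in that direction, and up to 4 members of each list with the smallest p. MIR17HG was not analysed here. The text describes the rule's genes in part. Members named because they passed over their list alone, and the genes with the largest fold changes, were chosen after their values were seen. A planned test of miR-20a seed sites in 3' untranslated regions was not run, since no such sequences were used here. The planned pseudocounts did not apply to log2 values.

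The gene and list tests were checked on simulated arrays of 12401 genes for miR-20a minus miR-NT, 200 of them changed, in 20 runs. Of the changed genes, 20.2% were recovered at a log2 fold of 0.5, 93.9% at 1 and 99.8% at 2, and 4.77% of the calls were false. A list of 30 genes shifted down by 0.2 was placed downward at an unadjusted camera p under 0.05 in 20 of 20 runs. An unshifted list reached that p in 1 of 20. The measured lists were called at an adjusted p instead. Simulated genes varied independently and by the same spread in both groups, with no difference across a whole array, which measured genes need not do. The share recovered also depends on the 200 planted changes, so it does not give the power in the measured data.

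Alternatives were quantile normalization, median centring, no filter on dim genes, the dimmest 50% left out, an intensity trend with a robust prior, the mean of a gene's probe sets, every probe set on its own, the replicate number as a block, each array left out in turn, stricter thresholds, and camera on ranks. The log2 signal of the ACTB 5' control probe set as a covariate and a test of 12 gene families were added after the data had been seen. The number of arrays limits the precision of every value.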

Results

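Gene expression was profiled in QK-knockdown Hs683 glioma cells that carried either miR-20a, a member of the miR-17 family of microRNAs, or a scrambled microRNA without a target (miR-NT). Each group held 2 arrays, and the comparison addressed which transcripts differ when miR-20a is added to cells with reduced QKI, an RNA-binding protein of glial cells. Over the 20323 probe sets the array medians were 6.45 and 6.45 with miR-NT and 6.43 and 6.45 with miR-20a on the log2 scale. The interquartile ranges were 3.14 and 3.03 with miR-NT and 3.06 and 2.92 with miR-20a, narrowest on miR-20a replicate 2. Pearson's r across probe sets, which are not independent replicates, was 0.997 between the miR-NT arrays and 0.996 between the miR-20a arrays. It was also 0.996 between miR-NT replicate 2 and miR-20a replicate 1. It was lowest, at 0.990, between miR-NT replicate 1 and miR-20a replicate 2.

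QKI, the gene knocked down in all 4 arrays, measured 8.14 and 7.92 with miR-NT and 7.52 and 7.08 with miR-20a. Its log2 fold change was −0.73 (SE 0.16), or 1.66-fold lower, and both miR-20a arrays lay below both miR-NT arrays, but it did not pass the limma test over all genes (adjusted p = 0.106). No array without the knockdown was analysed here, and which part of the transcript the probe set reads was not established. Fits with 1 array left out take the spread of a group from the other group, so only their log2 fold changes are given for QKI. The log2 fold change was −0.95 without miR-20a replicate 1 and −0.51 without miR-20a replicate 2. It was −0.62 without miR-NT replicate 1 and −0.84 without miR-NT replicate 2. With the ACTB 5' control signal as a covariate it was −0.06 (SE 0.25, limma adjusted p = 0.995). TGFBR2, the type II TGF-beta receptor and a published target of the miR-17 family, measured 8.83 and 8.62 with miR-NT and 8.69 and 8.50 with miR-20a. Its log2 fold change of −0.13 (SE 0.12) was within the spread between replicates (limma adjusted p = 0.534). With an array left out this fold change ranged from −0.24 to −0.02.

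Signal from control probe sets at the 5' ends of abundant transcripts, which is read as a sign of RNA or labelling quality, also differed between the groups. The ACTB 5' control measured 12.78 and 12.66 with miR-NT and 11.59 and 10.43 with miR-20a, 3.27-fold lower (log2 fold change −1.71, SE 0.31), with limma adjusted p = 0.110 over all probe sets. The GAPDH 5' control measured 13.89 and 13.81 with miR-NT and 13.17 and 12.30 with miR-20a, 2.16-fold lower (limma adjusted p = 0.133). Within the miR-20a pair, replicate 2 minus replicate 1 was −1.16 for ACTB 5' and −0.87 for GAPDH 5'.

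**Figure D1:**
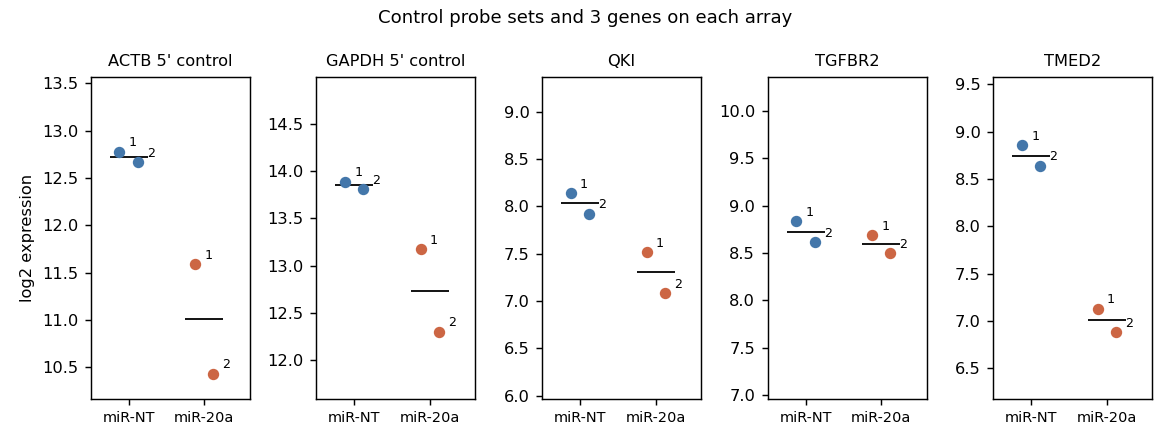
Log2 expression of the ACTB 5' and GAPDH 5' control probe sets and of QKI, TGFBR2 and TMED2 on each of the 4 arrays; points are arrays numbered by replicate and lines are group means (n = 2). The ACTB 5' control lies at 12.78 and 12.66 with miR-NT and at 11.59 and 10.43 with miR-20a, and the values of TMED2 do not overlap between the groups.

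TMED2, a cargo receptor of the p24 family that acts in transport between the endoplasmic reticulum and the Golgi, was the gene that passed the threshold. It fell from 8.75 ± 0.15 with miR-NT to 7.01 ± 0.18 with miR-20a (SD, n = 2 each, log2). This was a 3.35-fold difference (log2 fold change −1.74, SE 0.13, limma adjusted p = 0.0163). With the replicate number as a block TMED2 did not pass (limma adjusted p = 0.139). Next in the ranking of lower values, and short of the threshold, were IGFBP5, which binds insulin-like growth factors (log2 fold change −0.95), FUT8, the core fucosyltransferase of N-glycans (−0.92), the adhesion molecule NECTIN2 (−0.99), the sphingosine 1-phosphate phosphatase SGPP1 (−0.98) and the splicing factor SRSF1 (−0.97). Their adjusted p in limma ranged from 0.067 to 0.0727. No gene rose past the threshold, and the highest-ranked positive values were those of PLEKHH1 (log2 fold change 0.72), the cancer-testis antigen MAGEA8 (0.68), the imprinted gene PHLDA2 (0.61), FAM133A (0.58), TMEM87A (0.57) and IGFL2 (0.55), with limma adjusted p from 0.0727 to 0.0963. With miR-NT they measured 6.05, 5.46, 5.54, 7.92, 6.16 and 6.23 in that order, all but FAM133A below the array medians. The dimmest gene kept in the test had a mean of 5.46.

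Of 12401 genes tested with limma, 0 were higher and 1 was lower with miR-20a at an adjusted p under 0.05. At an unadjusted p under 0.05, 722 were higher and 1633 were lower, where chance gives about 620 in all; after quantile normalization these counts were 1584 and 1450. No gene was at least 2-fold higher and 66 were at least 2-fold lower. The groups did not overlap in 3117 genes with higher and 3852 with lower values, 56.2% of the genes where chance gives 33.3%. The 2 genes with the most negative log2 fold changes, chosen after their values were seen, had wide spreads with miR-20a, which TMED2, next in size, did not. P4HB, a disulfide isomerase of the endoplasmic reticulum, went from 9.41 ± 0.17 to 6.99 ± 1.17 and the glycolytic enzyme ENO1 from 11.32 ± 0.15 to 8.94 ± 1.22 (SD, n = 2 each), with limma adjusted p of 0.0949 and 0.0963. TMED2 lost its call without miR-NT replicate 1 (log2 fold change −1.64) or replicate 2 (−1.85). It kept the call without miR-20a replicate 1 (−1.87) or replicate 2 (−1.62). Such fits take the spread of a group from the other group, and the numbers of genes passing varied widely between them, so neither result decides the call.

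Genes of the extracellular matrix and cell adhesion were lower as a group with miR-20a. Of 30 tested members 23 had a log2 fold change below 0 and 7 above, with a median of −0.37 (1.29-fold lower; camera adjusted p = 0.00011, and adjusted p = 0.767 with an estimated correlation). Over all genes none passed, and adjusted over the list alone 17 fell and 2 rose. Among those that fell were the basement membrane collagen chains COL4A2 (log2 fold change −1.08, SE 0.15) and COL4A1 (−0.71, SE 0.13), the basement membrane linker NID1 (−0.63, SE 0.10), the integrin subunit ITGB1 (−1.34, SE 0.22) and the hyaluronan receptor CD44 (−0.87, SE 0.15). The 2 that rose were COL1A1, a chain of type I collagen (0.33, SE 0.11), and the interstitial collagenase MMP1 (0.34, SE 0.11). Within the miR-20a pair, the array with the lower ACTB 5' signal was also lower in the list's median, with a difference of −0.10. The median was −0.21 without a filter on dim genes, and −0.04 with the ACTB 5' signal as a covariate, where the call ended (camera adjusted p = 0.313). Over all alternatives the log2 fold changes came as near 0 as −0.20 for ITGB1, −0.20 for CD44 and −0.18 for COL4A1. For COL4A2 and NID1 the values nearest to 0 were −0.51 and −0.56.

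TGF-beta-induced genes, 8 of whose tested members are also in the matrix list, showed a median log2 fold change of −0.34 over 25 tested members, 19 below 0 and 6 above (camera adjusted p = 0.000153, and adjusted p = 0.767 with an estimated correlation). Over all genes none passed, and adjusted over the list alone 12 fell and 1, COL1A1, rose. IGFBP3, a binding protein of insulin-like growth factors, fell by 1.15 on the log2 scale (SE 0.15), THBS1, the matrix protein thrombospondin-1, by 0.61 (SE 0.10) and the collagen cross-linking enzyme LOX by 0.56 (SE 0.11) in that test. Across the alternatives, the values nearest to 0 were −0.54 for IGFBP3, −0.49 for THBS1 and −0.28 for LOX. The list's median differed by −0.17 within the miR-20a pair, lower in the array with the lower ACTB 5' signal. It was −0.11 without miR-20a replicate 2. The median was 0.03 with the ACTB 5' signal as a covariate, where that of all genes was 0.05, and the call ended (camera adjusted p = 0.604).

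Receptors and SMAD proteins of the TGF-beta pathway had a median log2 fold change of −0.16 over 27 members, 18 below 0 and 9 above, and were not called (camera adjusted p = 0.121). SMAD3, which carries the receptor signal to the nucleus, fell adjusted over the list alone (log2 fold change −0.89, SE 0.17), and no member passed over all genes. The value of SMAD3 came as near 0 as −0.09 over all alternatives. TGFB1 was at −0.47 (SE 0.12) and SMAD4, the common partner of the receptor-activated SMADs, at −0.51 (SE 0.14). Published targets of miR-17 and miR-20a had a similar median of −0.15 over 34 members, 22 below 0 and 12 above, and were not called either (camera adjusted p = 0.159). None of these targets passed over all genes or adjusted over the list alone, and the values with the smallest p were those of TIMP3 (log2 fold change −0.46), JAK1 (−0.40) and STAT3 (−0.59). With an array left out, the median ranged from −0.23 to −0.09 for the receptor and SMAD list, lowest without miR-20a replicate 1 and highest without replicate 2. It ranged from −0.15 to −0.07 for the targets, highest without miR-20a replicate 2. The medians of these 2 lists were 0.07 and 0.04 with the ACTB 5' signal as a covariate, and that of all genes was 0.05.

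Genes of G1/S and DNA replication were lower in 30 of 34 tested members, with a median log2 fold change of −0.16 (camera adjusted p = 0.00125, and adjusted p = 0.767 with an estimated correlation). Adjusted over the list alone 9 fell and 0 rose, and none passed over all genes. Among the 9 were thymidylate synthase TYMS (log2 fold change −1.07, SE 0.19), the replication factor subunit RFC3 (−1.24, SE 0.23) and the ribonucleotide reductase subunit RRM1 (−1.15, SE 0.22). Their values came as near 0 as −0.12, −0.26 and −0.05 over all alternatives. Genes of G2/M and mitosis were below 0 in 26 of 33 members, with a median of −0.12 (camera adjusted p = 0.0195, and adjusted p = 0.767 with an estimated correlation). Adjusted over the list alone 6 fell, among them the spindle checkpoint protein MAD2L1 (−1.31, SE 0.30), and 1 rose, ECT2 (0.42, SE 0.09). ECT2 measured 5.54 with miR-NT, where the dimmest gene kept had a mean of 5.46. Within the miR-20a pair the medians of the G1/S and G2/M lists differed by −0.17 and −0.18, both lower in the array with the lower ACTB 5' signal. The G2/M call ended after quantile normalization (median −0.04, camera adjusted p = 0.165), without miR-NT replicate 1 (−0.10, 0.0556) and without miR-20a replicate 2 (−0.09, 0.0721), and its median was −0.07 after median centring, −0.21 without miR-NT replicate 2 and −0.24 without miR-20a replicate 1. The G1/S median was −0.09 after quantile normalization and −0.10 without miR-20a replicate 2. Both calls ended with the ACTB 5' signal as a covariate, at medians of 0.04 (G1/S, camera adjusted p = 0.954) and 0.10 (G2/M, 0.82), where that of all genes was 0.05.

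Genes induced by hypoxia were below 0 in 21 of 24 tested members, with a median log2 fold change of −0.18 (camera adjusted p = 0.00129, and adjusted p = 0.767 with an estimated correlation). Over all genes none passed, and adjusted over the list alone 6 fell and 0 rose. These were the glycolytic enzymes PGK1 (log2 fold change −0.89, SE 0.16) and ENO1 (−2.38, SE 0.46), LOX (−0.56, SE 0.11), the mitophagy receptors BNIP3 (−0.37, SE 0.10) and BNIP3L (−0.42, SE 0.12), and the angiogenic factor VEGFA (−0.38, SE 0.11). Within the miR-20a pair, whose ACTB 5' signals differed by −1.16, the list's median differed by −0.01 and its mean by −0.08; 14 of the 24 members were lower in the array with the lower ACTB 5' signal. The 6 genes, chosen by a fold change that holds the same arrays, were all among these 14, with a difference of −1.72 for ENO1, −0.48 for PGK1, −0.18 for LOX, −0.17 for VEGFA, −0.11 for BNIP3L and −0.10 for BNIP3. With the ACTB 5' signal as a covariate the list's median was −0.16 and the call was kept (camera adjusted p = 0.0148). In that fit ENO1 was at 0.16 and PGK1 at −0.17.

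Proteins of the microRNA pathway were lower in 9 of 11 tested members, with a median log2 fold change of −0.27 (camera adjusted p = 0.0317, and adjusted p = 0.767 with an estimated correlation). Adjusted over the list alone 3 fell, the precursor exporter XPO5 (log2 fold change −0.49, SE 0.12), GEMIN4 (−0.47, SE 0.14) and the silencing-complex protein TNRC6A (−0.46, SE 0.14), and none passed over all genes. Within the miR-20a pair the median differed by −0.31, with all 11 members lower in the array with the lower ACTB 5' signal. The call ended after quantile normalization (median −0.19, camera adjusted p = 0.066), with the dimmest 50% left out (−0.25, 0.153), without miR-NT replicate 1 (−0.24, 0.0711) and without miR-20a replicate 2 (median −0.09, 0.288). The median was −0.44 without miR-20a replicate 1, and with the ACTB 5' signal as a covariate it was 0.23 (camera adjusted p = 0.571). GEMIN4 turned to 0.09 with that covariate, and over all alternatives XPO5 and TNRC6A came as near 0 as −0.03 and −0.16.

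**Figure D2:**
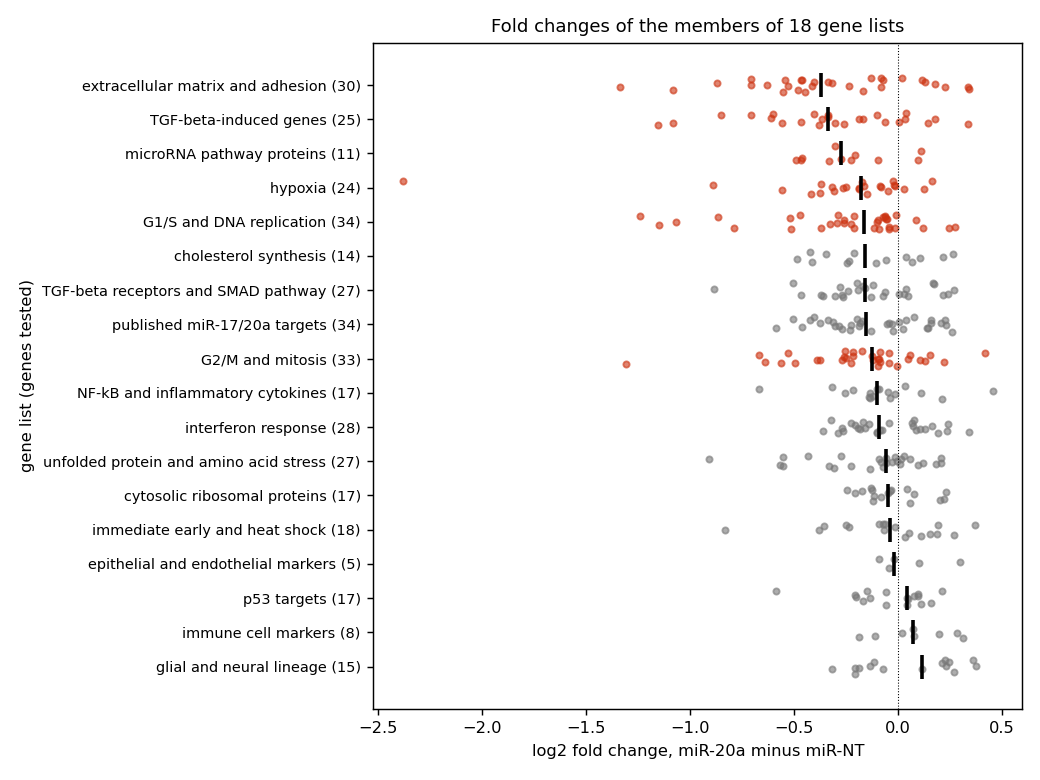
Log2 fold change, miR-20a minus miR-NT, of each tested member of 18 gene lists, ordered by median; points are genes, black bars are list medians, and red marks lists past the camera threshold at the preset correlation. The matrix list has the lowest median, −0.37 over 30 genes, and the glial and neural list the highest, 0.12 over 15 genes, which turned to −0.16 with the dimmest 50% left out.

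The other lists were not called. Glial and neural lineage genes had a median log2 fold change of 0.12 over 15 members, 8 above 0 and 7 below (camera adjusted p = 0.241), with PDGFRA at 0.37 (SE 0.09) and CSPG4 at 0.36 (SE 0.12). Both are markers of oligodendrocyte precursors, but they measured only 5.59 and 5.79 with miR-NT, where the dimmest gene kept had a mean of 5.46. The lineage genes OLIG1 and OLIG2 were left out as dim. The list's median was −0.16 with the dimmest 50% left out, 0.025 without miR-20a replicate 1 and 0.038 without replicate 2. Immune cell markers had a median of 0.07 over 8 members (adjusted p = 0.232), and passed without miR-NT replicate 2 (median 0.13, camera adjusted p = 0.0481). Epithelial and endothelial markers had a median of −0.02 over 5 members and a mean of 0.05 (adjusted p = 0.562). Cholesterol synthesis genes had a median of −0.16 over 14 members (camera adjusted p = 0.241), from −0.20 to −0.08 with an array left out. Adjusted over the list alone 3 fell, INSIG1 (−0.49), DHCR7 (−0.42) and EBP (−0.42). Unfolded protein and amino acid stress genes had a median of −0.06 over 27 members (adjusted p = 0.205), and 4 fell adjusted over the list alone, PSAT1, an enzyme of serine synthesis (−0.91), the chaperone CALR (−0.57), the disulfide isomerase PDIA6 (−0.55) and TRIB3 (−0.56). Immediate early and heat shock genes had a median of −0.04 over 18 members, which camera placed upward (adjusted p = 0.936), and 1 fell adjusted over the list alone, the matricellular protein CCN1 (−0.83, SE 0.19). Medians were −0.09 for 28 interferon response genes (camera adjusted p = 0.751) and −0.10 for 17 NF-kB and inflammatory cytokine genes (0.397). That of 17 cytosolic ribosomal proteins was −0.05 (camera adjusted p = 0.936). With an array left out these medians ranged from −0.12 to −0.04 (interferon), −0.15 to −0.02 (NF-kB) and −0.11 to −0.008 (ribosomal). The 17 p53 targets had a median of 0.04 and a mean of −0.04, and camera placed them upward (adjusted p = 0.936).

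**Figure D3:**
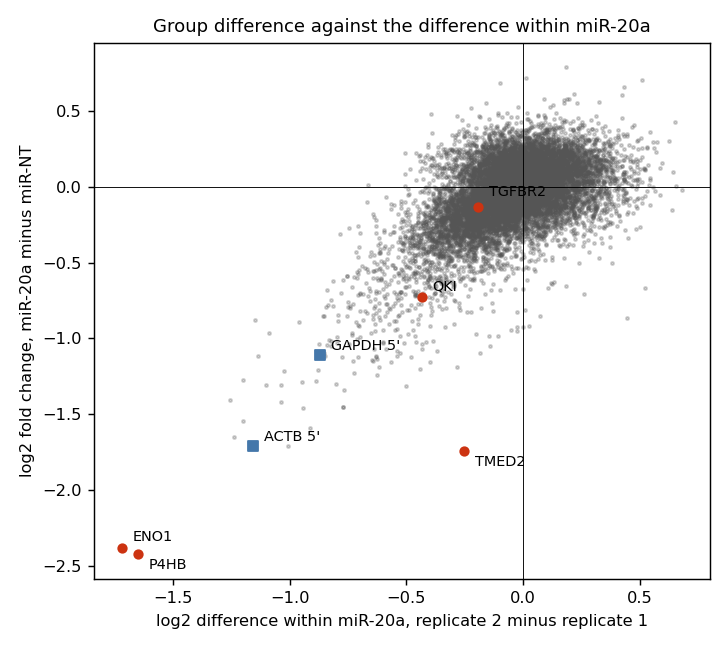
Log2 fold change, miR-20a minus miR-NT, against the log2 difference within the miR-20a pair, replicate 2 minus replicate 1, for each of 12401 tested genes and for the ACTB and GAPDH 5' control probe sets (squares). Both axes hold the miR-20a arrays, and Pearson's r across genes, which are not independent replicates, is 0.549; TMED2 lies apart, with a fold change of −1.74 and a pair difference of −0.25.

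Across the 12401 genes, which are not independent replicates, the log2 fold change and the difference within the miR-20a pair (replicate 2 minus replicate 1) had a Pearson's r of 0.549 and a Spearman's rho of 0.463. Both quantities hold the miR-20a arrays, so that r lies above 0 without any change where replicate 2 varies more than replicate 1. When the change was taken from miR-20a replicate 1 alone, which pushes r below 0 through the shared array, Pearson's r was 0.132 and Spearman's rho 0.054. For ENO1 the miR-20a arrays measured 9.80 and 8.08.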

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

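The ACTB 5' covariate was chosen after the data had been seen; the other settings were planned, and the seed-site test, its alternatives and the pseudocounts were not run. Of 1056 values of the 90 named genes under an alternative, 906 kept direction and side of the threshold, 117 passed it newly, 3 fell short and 30 reversed; of 252 list medians 209 kept both, 1 passed newly, 14 fell short and 28 reversed. The cause of these changes was not tested, except where stated. Numbers of genes lower, 1 as reported, were 6 after quantile normalization, 4 with the dimmest 50% left out (fewer genes tested), 23 with an intensity trend and a robust prior, 0 at an adjusted p under 0.01 and 5 with the 5' covariate; 1 was higher with the trend and robust prior and 1 with the covariate. With an array left out, genes higher ranged from 0 to 302 and genes lower from 0 to 1567: without either miR-20a array the spread came from the miR-NT pair, and the prior degrees of freedom were 28.3 against 5.44 without a miR-NT array. The lone array of a group was assumed to vary like the other group. Called lists numbered 0 with an estimated correlation and 1 with the 5' covariate, against 6 as reported. How far these arrays stood above background was not analysed here.

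The labels do not say whether equal replicate numbers mark a shared day or culture. Across genes the deviations of same-numbered arrays correlated at 0.267, which with 2 arrays per group does not settle it. With the replicate block 0 genes were higher and 0 lower, TMED2 had an adjusted p of 0.139, and 6 lists were called.

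With an estimated correlation the medians stayed as they were, −0.34 for TGF-beta-induced genes, −0.37 for matrix, −0.16 for G1/S, −0.12 for G2/M, −0.18 for hypoxia and −0.27 for microRNA pathway genes, and all 6 had adjusted p = 0.767. The adjustment tied them, since their unadjusted camera p ranged from 0.128 (hypoxia) to 0.458 (microRNA pathway). Their correlations, from 0.07 (hypoxia) to 0.76 (microRNA pathway), were estimated with 2 residual degrees of freedom. Quantile normalization, which moved the median of all genes from −0.023 to 0.027, ended the calls of G2/M (−0.040) and microRNA pathway genes (−0.19), and turned the medians of unfolded protein (0.022), immediate early (0.042), epithelial and endothelial (0.11) and ribosomal genes (0.020), and KRT8 (0.013); values near 0 turn with such a shift. Median centring turned immediate early (0.014), epithelial and endothelial (0.031) and ribosomal genes (0.0018) and KRT8 (0.0080). With the dimmest 50% left out the microRNA pathway call ended (−0.25), and p53 targets (−0.0094) and glial and neural genes (−0.16) turned; p53 targets also turned with the mean of a gene's probe sets (−0.0094). With an array left out, medians ranged from −0.24 to −0.092 for G2/M, −0.44 to −0.093 for microRNA pathway genes, −0.024 to 0.028 for p53 targets, −0.10 to 0.020 for unfolded protein, −0.066 to 0.018 for immediate early, −0.095 to 0.073 for epithelial and endothelial and 0.0070 to 0.16 for immune genes, and log2 fold changes from −0.079 to 0.28 for KRT5 and −0.22 to 0.13 for KRT8.

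With the 5' covariate the matrix median was −0.040 and its call ended, and medians turned for miR-17/20a targets (0.042), TGF-beta receptors and SMAD pathway (0.074), TGF-beta-induced (0.030), G1/S (0.045), G2/M (0.10), interferon (0.14), NF-kB (0.094), unfolded protein (0.13), immediate early (0.13), immune (−0.067), epithelial and endothelial (0.11), ribosomal (0.085) and microRNA pathway genes (0.23). The median of all genes was then 0.047, and camera still placed miR-17/20a targets, TGF-beta-induced and G1/S genes downward. Log2 fold changes that turned were those of TGFBR2 (0.18), STAT3 (0.047), SMAD4 (0.074), MAD2L1 (0.32), BAX (0.45), CCNG1 (0.0089), PPM1D (0.27), SAMD9 (0.11), NFKB1 (0.22), ICAM1 (0.036), ENO1 (0.16), EBP (0.036), TRIB3 (0.10), CCN1 (0.096), DNAJB1 (0.044), MYC (0.17), AIF1 (−0.039), KRT5 (−0.46), KRT8 (0.49), RPS9 (0.013), GEMIN4 (0.090), PRKRA (0.23), P4HB (0.023), ANP32E (0.18) and EGFR (−0.11). Over all its alternatives the log2 fold change of TMED2 ranged from −1.87 to −1.35. It was not called with the replicate block, at an adjusted p under 0.01 or without either miR-NT array.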

Other observations

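In this part, the gene families, the covariate fit, the tests of QKI and TMED2, the correlation over all genes and the final forms of the list tests of 5' signal loss and of compression were chosen after the results had been seen. The planned bound on compression, 95% of resampled member sets below the 5th percentile of matched lists after quantile normalization, was reached by none of the 6 lists (30.6% to 92.5%). Gene families, defined by the start of their symbols, were refined once after a first look by leaving out pseudogenes and associated factors, which left the same families called. Subunits of the proteasome, the complex that degrades ubiquitinated proteins, had a median log2 fold change of −0.18 over 30 genes, 26 below 0 (camera adjusted p = 0.00736, 0.249 after quantile normalization, and adjusted p = 0.927 with an estimated correlation). PSMC3 was at −0.82 (SE 0.20) and PSMD10 at −0.53 (SE 0.10), and within the miR-20a pair the family's median differed by −0.17. Keratins had a median of 0.05 over 23 genes, 17 above 0 (adjusted p = 0.0433, 0.249 after quantile normalization, and adjusted p = 0.927 with an estimated correlation), led by KRT2 (0.39, SE 0.11), KRT77 (0.36, SE 0.10) and KRT75 (0.34, SE 0.11), 3 keratins at 5.87, 5.32 and 6.23 with miR-NT. Of the other 10 families none was called. Of the 7 TMED genes tested, TMED2 was called, while TMED4 was at 0.31 (SE 0.10), TMED9 at 0.21 (SE 0.10) and TMED10 at −0.16 (SE 0.10); 4 were above 0 and 3 below. Outside the gene test, 2260 probe sets with several genes or none gave 0 higher and 0 lower at a limma adjusted p under 0.05, and 133 higher and 245 lower unadjusted.

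The 6 lists called at the preset correlation were all lower with miR-20a, as was the 5' signal of ACTB and GAPDH; none was called with an estimated correlation (adjusted p = 0.767 each), which the matched random lists do not take into account. Compression of bright probe sets was not settled as the whole cause, since no list reached the planned bound. Under the bound chosen after the values were seen, 4 lists went against it, still called at the preset correlation after quantile normalization. Their medians were −0.27 (TGF-beta-induced), −0.28 (matrix), −0.09 (G1/S) and −0.12 (hypoxia). They lay at percentiles of 0.01, 0.01 (the smallest that 10000 random lists can give), 0.48 and 0.17 of expression-matched lists. Their resampling intervals ended below the medians of those lists, for hypoxia at −0.043 against 0.021. The others ended narrowly below, at 0.005 against 0.022 (TGF-beta-induced), 0.004 against 0.018 (matrix) and 0.012 against 0.019 (G1/S). Members were resampled as if independent. Compression may account for G2/M (percentile 9.28) and stays open for the microRNA pathway (0.52), whose call ended. Loss of 5' signal stays open. Within the miR-20a pair the medians of 4 lists lay at percentiles of 0.99 (TGF-beta-induced), 1.25 (G1/S), 1.26 (G2/M) and 0.03 (microRNA pathway). These lists were called by a fold change that holds the same arrays. The random lists were matched on expression only, so low percentiles can come in part from that choice. Over all genes the change in miR-20a replicate 1 correlated with the pair difference at 0.132 (Pearson's r, 95% resampling interval 0.105 to 0.16). Spearman's rho was 0.054. That interval resamples genes, which are not independent, and does not measure the spread between arrays. These values go with 5' signal loss, but a stronger response to miR-20a in replicate 2 would give the same. For matrix (percentile 36.3) and hypoxia (98.7) the pair's medians, −0.10 (interval −0.24 to −0.03) and −0.01 (−0.10 to 0.06), lay short of the −0.25 and −0.12 that would follow ACTB 5', but the intervals of their means, −0.23 to −0.09 and −0.24 to 0.06, held the expected −0.22 and −0.20, and ENO1 in the hypoxia list differed by −1.72 where −1.61 would follow ACTB 5'. An effect of miR-20a beyond the 5' signal also stays open. With the ACTB 5' covariate 1 of the 6 lists, hypoxia, was still called lower at the preset correlation. Its median was −0.16, from −0.18 (camera adjusted p = 0.0148). This fit cannot decide whether 5' loss was the whole cause for hypoxia. The ACTB 5' signal separates the groups completely, its slope rests mostly on the same pair, and the fit kept 1 residual degree of freedom.

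QKI was 1.66-fold lower with miR-20a in cells where it was already knocked down. If its fold change had followed ACTB 5', the miR-20a pair would differ by −0.49; it differed by −0.43, where the SD of a pair difference was 0.22, which is consistent with 5' signal loss or with a stronger response in replicate 2. With the ACTB 5' covariate the log2 fold change of QKI was −0.06 (SE 0.25), from −0.73 (SE 0.16). An effect of miR-20a on QKI, direct or not, and a difference in knockdown between the cultures were not tested and remain possible.

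TMED2 was called at −1.74 on the log2 scale, but not with the replicate number as a block (limma adjusted p = 0.139). Had it followed ACTB 5', the miR-20a pair would differ by −1.18, and it differed by −0.25 (SD of a pair difference 0.18), in the direction of 5' signal loss but smaller. With the ACTB 5' covariate it stayed called, at −1.35 (SE 0.25, limma adjusted p = 0.000282), in a fit that gave every gene the same variance. Without miR-NT replicate 1 or 2 the call was lost at about the same fold (−1.64 and −1.85). It was kept without miR-20a replicate 1 or 2 (−1.87 and −1.62). Fits with 1 array left out take the spread of a group from the other group, so they do not decide the call. Neither 5' signal loss in part nor an effect of miR-20a is excluded by these values from a single gene, so that a response of TMED2 to miR-20a is a hypothesis for a separate measurement.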
